A study of Drosophila melanogaster with 4 samples.

How the data were processed

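ChIP followed by sequencing was used on nuclei of adult fly heads, with 2 ChIP and 2 input libraries. Per the labels' protocols, heads were sieved from adults of population cages, homogenized and fixed with formaldehyde, and the chromatin was sonicated before immunoprecipitation. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The authors deposited 3 lists of regions of significant enrichment in GFF3 format, on the genome build FlyBase r5, per the file headers. One list belongs to each ChIP replicate, and the labels of the inputs say that each input served the ChIP of the same number. The third belongs to the replicate set, and whether it was called on pooled reads is not given in the sources used here. The caller, its threshold, its treatment of repeats and duplicate reads, and its minimum length are likewise not given in the sources used here. The shortest cluster was 1301 bp in both replicate lists and 1001 bp in the replicate-set list, so features shorter than this were not listed.

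Each deposited cluster carries 1 score from the authors. Its scale and log base are not stated in the files, so scores served only to rank and compare clusters and were never turned into folds. In the 3 lists the scores ran from 0.0609 to 3.47. A score may be lower in the replicate-set list for reasons of construction, and scores were therefore not compared in level between that list and the others. Read counts were not given, so depth is unknown and no interval for a cluster's enrichment could be made.

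The lists were read as intervals. Clusters within the replicate lists did not overlap each other, and 5 neighbours did in the replicate-set list and were merged. No cluster had the same start and end in both replicate lists. The headers name 14 sequences with their lengths (168.7 Mb), and these lengths were the denominators for coverage. The main arms 2L, 2R, 3L, 3R and X sum to 119.0 Mb. Centromere ends were taken as the high coordinates of 2L, 3L and X and the low coordinates of 2R and 3R. The main value of each comparison between arms used the sequence found in both replicate lists, and an overlap of 1 bp counted a cluster as shared.

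Agreement of the lists was tested by 1000 circular shifts of one list within each sequence. Differences in coverage were tested by permuting 500-kb windows 100000 times between X and the autosomal arms, or within arms between the third nearest the centromere and the rest. Benjamini-Hochberg adjustment ran over the 6 tests of this family. The interval of the score correlation came from resampling windows 1000 times, intervals of mean differences from resampling them 10000 times, and those of shares of clusters are Wilson intervals at 95%. The tests were checked on simulated data. Of 20 lists with randomly placed clusters, 0 passed the threshold of the shift permutation test. A list with 50.3% of replicate 1 clusters kept in place gave a permutation p of 0.01, the smallest that its 100 shifts allow. With no difference between arms, 2 of 100 simulated sets of windows were called, and with X lowered by 30% all 100 were. These windows came from randomly placed clusters and were shuffled before the X label was set, so a low rate of false calls was built in. The check covers the running of the window test, and not its error rate or power on real windows, where clusters may clump. The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

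The comparisons, their alternatives and the rule for naming regions were fixed before the data were examined, except where a comparison is said to have been added. The rule named the 10 regions with the highest lower-of-both scores, the 5 longest regions in both lists and the 3 highest-scoring clusters of each replicate list with no base in the other. It had been written for genes, with regions by coordinates as the fallback. For the first part, clusters of the replicates had to overlap each other by at least 50%, and the parts on gene lists and single genes could not be applied. The gene table at hand is on release 6 of the genome, and coordinates of different releases cannot be combined. For this reason the planned comparisons of genomic features, position within genes, gene length and 18 gene lists were not made.

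Alternatives were a stricter score (upper 50% or 25% of each list), other overlap rules, merging of close clusters, 100-kb windows, the union, each replicate list alone, the replicate-set list, leaving out sequence near the centromere, and a common lower score limit for X and autosomal clusters of like length, taken from the X clusters (also applied to autosomal clusters alone).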

Results

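The data describe where histone H4 monomethylated at lysine 20 (H4K20me1) was enriched in chromatin of adult fly heads. H4K20me1 is a mark that the methyltransferase PR-Set7 places on chromatin. The heads came from the wild-type Oregon-R strain of Drosophila melanogaster, collected as mixed adults. The series has 4 libraries. There were 2 chromatin immunoprecipitation (ChIP) replicates made with the 3rd antibody lot, and 2 input replicates that hold chromatin without immunoprecipitation. Each ChIP replicate came with a list of enriched clusters called against the input of the same number, and a further list covered the replicate set. The inputs entered the analysis through those calls alone. Nothing in the labels says whether the replicates came from separate fly collections, so differences between them may be technical. Read totals were not given, so the depth behind each cluster is unknown. Coordinates are those of FlyBase release 5, counted from 1.

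H4K20me1 clusters covered a similar share of the main chromosome arms in both replicates. Replicate 1 held 6426 clusters over 33.0 Mb and replicate 2 held 6799 clusters over 33.5 Mb. These clusters covered 27.6% and 27.9% of the 5 main arms (2L, 2R, 3L, 3R and X). The median cluster was 3061 bp long in replicate 1 and 2954 bp in replicate 2, and the longest reached 106159 and 86986 bp. Clusters of 10 kb or more made up 39.6% of the covered length in replicate 1 and 38.3% in replicate 2. Longer clusters carried higher scores from the authors' caller, with Spearman's rho across clusters of 0.74 in both lists (Pearson's r of score with log10 length, 0.66 and 0.69). Clusters are not independent replicates, and no p-value was computed for this relation.

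The first comparison asked whether the 2 ChIP replicates marked the same parts of the genome. Shared sequence amounted to 27.9 Mb of the 38.6 Mb that lay in either list, a Jaccard index of 0.722. When one list was shifted at random around each chromosome, the index averaged 0.163 ± 0.006 (SD over 1000 shifts) and never exceeded 0.238. The one-sided permutation p was 0.001, the smallest that 1000 shifts can give (0.0015 after Benjamini-Hochberg adjustment over 6 tests). Of the replicate 1 clusters, 85.1% touched a replicate 2 cluster (95% Wilson interval 84.2 to 85.9), and 82.9% of the replicate 2 clusters touched one of replicate 1 (82.0 to 83.8). These intervals cover counting error over clusters only. Only the Jaccard index was compared with shifted lists, so how many clusters would touch at random is not known. The unshared clusters were shorter and scored lower. A longer cluster is more likely to touch another, and scores rose with length, so both contrasts are partly built into the 1-bp rule. Their median length was 1786 bp against 3544.5 bp for shared clusters in replicate 1, and 1692 against 3497 bp in replicate 2. Their median score was 0.679 against 0.929 in replicate 1, and 0.792 against 1.01 in replicate 2.

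Coverage of 500-kb windows was closely matched between replicates, while scores of single clusters correlated less. The first sums many clusters and the second takes them singly, so the correlations are not on a like scale. Across 236 windows of 500 kb, the covered share of replicate 1 correlated with that of replicate 2 at r = 0.968 (Spearman's rho 0.958). The ends of 5466 best-overlapping cluster pairs differed by a median of 489.5 bp at the start and 506 bp at the end. Their scores correlated with a Spearman's rho of 0.613 (95% interval 0.590 to 0.636 from resampled windows) and a Pearson's r of 0.682. Within chromosomes rho was 0.686 on 3R, 0.671 on 2R, 0.664 on 3L, 0.567 on 2L and 0.392 on X. Windows and clusters are not independent replicates.

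**Figure D1:**
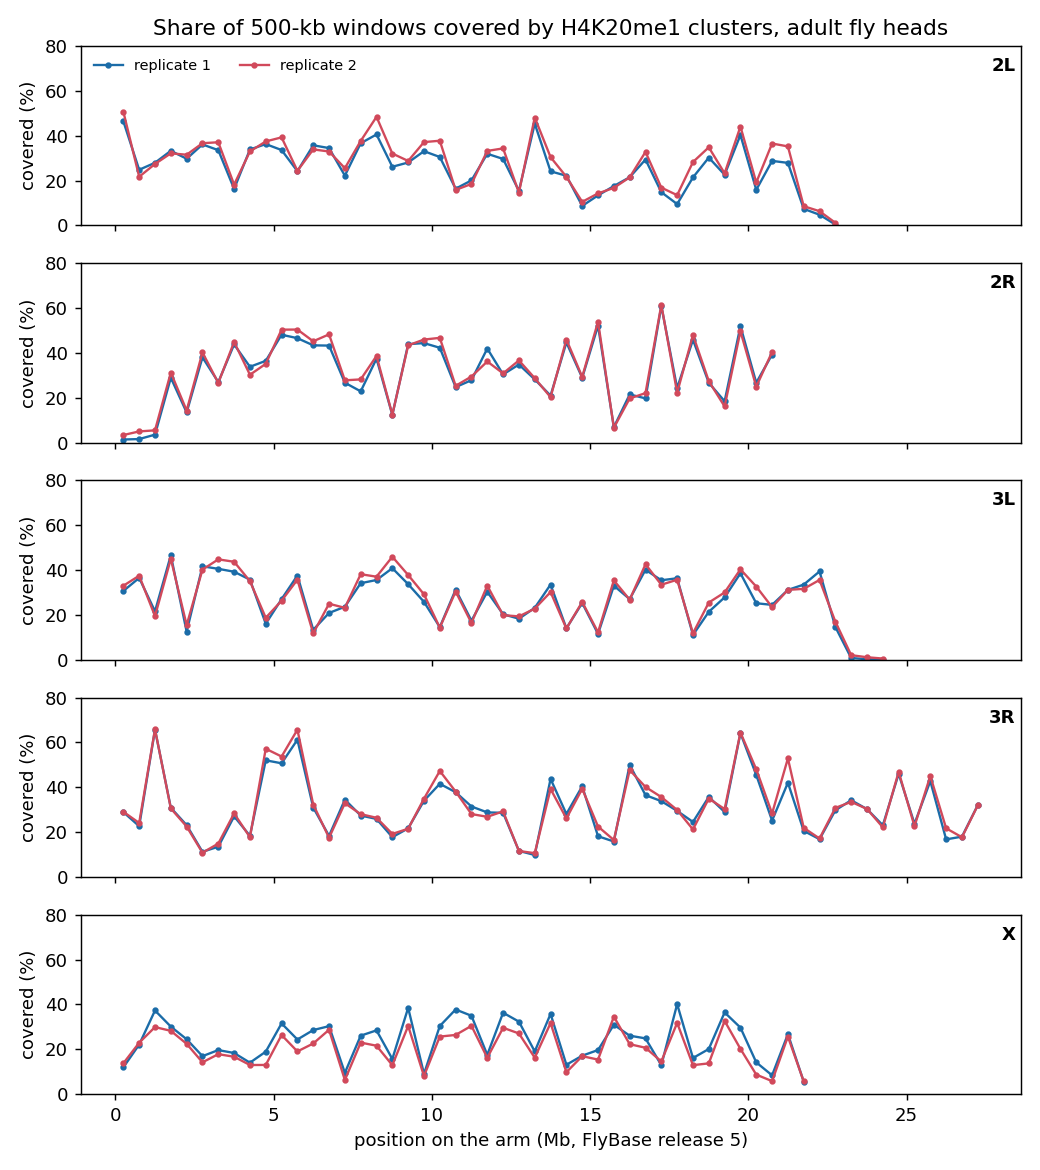
Share (%) of each 500-kb window covered by H4K20me1 clusters, plotted along each main arm in Mb; each point is 1 window and each line 1 replicate list. The lines of the replicates run together, the highest windows lie on 3R and 2R, and on X replicate 1 lies above replicate 2 in most windows.

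A small number of long regions held much of the marked sequence. The intersection of both lists formed 6711 regions with a median length of 2546 bp. Of these, 543 were at least 10 kb long and held 33.2% of the intersected length, 124 were at least 20 kb and 7 were at least 50 kb. All 7 lay on autosomal arms. The longest ran on 2R from 17281513 to 17368498 (86986 bp), with scores of 1.36 in replicate 1 and 1.63 in replicate 2. The next was on 3L from 22324468 to 22401435 (76968 bp), followed by 2L from 12454914 to 12520721 (65808 bp), 3R from 5751776 to 5815277 (63502 bp) and 3L from 17086641 to 17140983 (54343 bp). The region on 3R had the highest scores of these, 2.44 and 2.06.

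The 10 regions with the highest scores were not among the 5 longest. They ran from 4899 to 24418 bp, above the median of 2546 bp for regions in both lists. Regions were ranked by the lower of their 2 replicate scores among clusters that each overlapped the other by at least 50%. The first was on 3R from 255374 to 260272, with scores of 2.82 in replicate 1 and 2.67 in replicate 2. It was followed by 2R from 5454894 to 5469808 (2.59 and 2.70), 2R from 5575273 to 5580996 (2.61 and 2.54), 2R from 10747981 to 10759226 (2.54 and 2.51) and 2L from 2979096 to 2989935 (2.81 and 2.47). A 20127-bp region on 3R from 20054367 to 20074493 scored 2.89 and 2.42. The remaining 4 of the first 10 were 3L from 19786805 to 19792782, 2R from 12515835 to 12523792, 3L from 16776282 to 16800699 and 2L from 21677388 to 21682464, with lower scores between 2.35 and 2.41. No region of X or chromosome 4 was among the first 10. All 10 also overlapped a cluster of the replicate-set list. That list held 99.98% of the sequence found in both replicate lists, so this overlap adds no support. The genes in these regions are not given, because no annotation of release 5 was used here.

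The X chromosome, of which males carry a single copy, was covered less than the large autosomal arms (2L, 2R, 3L and 3R), though more than chromosome 4. Sequence found in both lists covered 16.2% of X against 24.96% of the autosomal arms, a ratio of 1.54. Single arms stood at 27.2% for 3R, 27.0% for 2R, 22.9% for 3L and 22.6% for 2L. Over 500-kb windows, the mean was 16.4% ± 7.26 on X (SD, 44 windows) and 24.99% ± 11.7 on the autosomal arms (192 windows). The difference was -8.59 percentage points (95% interval -11.3 to -5.84 from resampled windows; two-sided permutation p = 1e-05, the smallest that 100000 permutations can give; adjusted p = 2e-05). Replicate 1 alone gave 23.4% on X against 28.6% on the autosomal arms, and replicate 2 gave 19.9% against 29.7%. Over windows the difference was -4.91 points for replicate 1 alone (permutation p = 0.0156) and -9.61 points for replicate 2 alone (permutation p = 1e-05). In the replicate-set list the difference was -4.03 points and did not pass the threshold (permutation p = 0.0723). X was the lowest of the 5 arms in every list, although 1 arm among 5 cannot give an exact one-sided p below 0.2. Windows are not biological replicates, and these p-values compare parts of the genome within the same libraries.

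**Figure D2:**
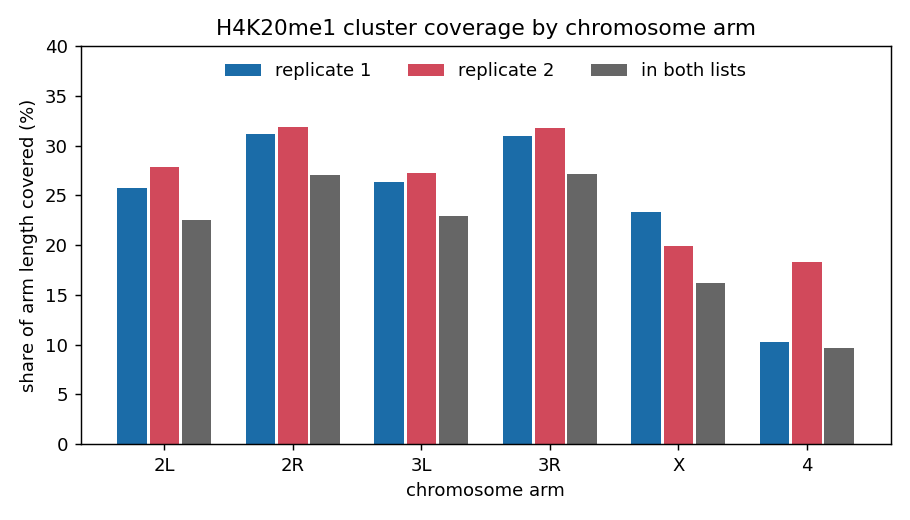
Share (%) of each chromosome arm covered by H4K20me1 clusters; bars show replicate 1, replicate 2 and the sequence found in both lists. X stands at 23.4%, 19.9% and 16.2%, below the other main arms, and chromosome 4 at 10.3%, 18.3% and 9.71%.

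Long regions were scarce on X, while short ones were not. Regions of 10 kb or more covered 2.15% of X and 9.08% of the autosomal arms, a ratio of 4.21. Over windows the means were 2.20% ± 3.03 (SD, 44 windows) and 9.09% ± 7.21 (SD, 192 windows), a difference of -6.89 points (95% interval -8.25 to -5.56; two-sided permutation p = 1e-05, adjusted p = 2e-05). X held 30 of the 543 such regions, 5.52% of them, with 18.8% of the main-arm length. Its longest region ran from 2528172 to 2568750 (40579 bp) and ranked 16th in length among all regions. Regions of 3 to 10 kb also covered less of X, 7.39% against 10.8% of the autosomal arms. Regions under 3 kb covered 6.61% of X and 5.10% of the autosomal arms. The number of regions per Mb was 56.6 ± 23.8 on X and 55.9 ± 22.96 on the autosomal arms over the same windows (SD; permutation p = 0.863). This density depended on the list, as X exceeded the autosomal arms by 7.14 clusters per Mb in replicate 1 alone (permutation p = 0.0390), by 15.8 in the replicate-set list (permutation p = 2e-05) and by 10.5 in the union (permutation p = 0.00145). In replicate 2 alone the difference was 4.02 (permutation p = 0.271), and in the upper 25% by score it was -4.70 (permutation p = 5e-05). The ratio for clusters of 10 kb or more depended on the list, at 2.20 in replicate 1, 5.00 in replicate 2 and 1.91 in the replicate-set list. This comparison by length and that of region density were added after the data were seen.

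**Figure D3:**
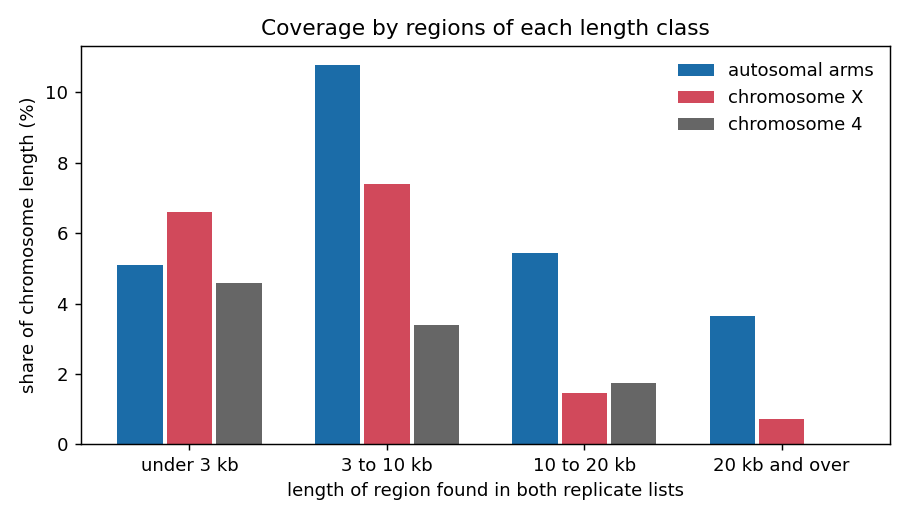
Share (%) of chromosome length covered by regions found in both replicate lists, by region length class; bars show the autosomal arms, X and chromosome 4. X exceeds the autosomal arms for regions under 3 kb (6.61% against 5.10%). It lies below them at 3 to 10 kb (7.39% against 10.8%), at 10 to 20 kb (1.44% against 5.44%) and at 20 kb and over (0.711% against 3.63%).

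The replicates shared less of their marked sequence on X than on the large autosomal arms. The Jaccard index was 0.597 on X, ranged from 0.727 on 2L to 0.763 on 3R, and was 0.515 on chromosome 4. Averaged over windows, it was 0.582 ± 0.108 on X (SD, 44 windows) and 0.724 ± 0.118 on the autosomal arms (192 windows), a difference of -0.142 (two-sided permutation p = 1e-05, adjusted p = 2e-05; added after the data were seen). The index was not matched for cluster length. X clusters were shorter, with medians of 2630.5 bp in replicate 1 and 2396 bp in replicate 2, against 3242 and 3187 bp on the autosomal arms. Differences at cluster ends weigh more on short clusters, so length may account for part of the lower index. Of the 1316 X clusters of replicate 1, 335 (25.5%) had no base in replicate 2, against 11.4% to 13.2% on the autosomal arms. Of the 1322 X clusters of replicate 2, 197 (14.9%) had no base in replicate 1, against 15.9% to 18.1% on the autosomal arms.

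Chromosome 4, a small and largely heterochromatic autosome, was marked over 10.3% of its length in replicate 1 and 18.3% in replicate 2. The 43 clusters of replicate 1 were nearly all present among the 63 of replicate 2, since 2 of them had no overlap, whereas 31 clusters of replicate 2 were absent from replicate 1. Sequence found in both lists covered 9.71% of the chromosome. The scaffolds of heterochromatic and unplaced sequence held 24 clusters in replicate 1 and 36 in replicate 2, and 0.0845% of their 48335474 bp was covered in both. How reads from repeated sequence were treated was not given in the sources used here. The 2 clusters on the Y scaffold, from 305885 to 307264 and from 339422 to 341536, were in replicate 1 and absent from replicate 2.

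Coverage fell off at the centromere end of several arms. The window of 2L from 22500001 to 23000000 was covered to 0.402% in replicate 1 and 1.17% in replicate 2. That of 2R from 1 to 500000 was covered to 1.39% and 3.38%, and that of 3L from 23500001 to 24000000 to 0.265% and 1.15%. On 3R the window from 1 to 500000 was covered to 28.9% and 29.1%. Over the windows in the third of each arm nearest the centromere, the mean in both lists was 21.5% ± 13.2 (SD, 78 windows) against 24.3% ± 10.4 in the rest (158 windows). This difference of -2.77 points did not pass the threshold (two-sided permutation within arms, p = 0.0509, adjusted p = 0.0610). Replicate 1 alone gave -3.54 points (permutation p = 0.0256) and replicate 2 alone -2.96 points (p = 0.0633 by permutation). Without the 2 Mb of each arm nearest the centromere the difference was 0.258 points (permutation p = 0.957).

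The clusters with the highest scores among those found in 1 list lay mostly on unplaced sequence and X. In replicate 1 they were on U from 7528530 to 7530281 (score 2.19), on X from 19921646 to 19922998 (2.06) and on X from 10809416 to 10813132 (1.95). In replicate 2 they were on U from 5831809 to 5833801 (2.01), on U from 10012573 to 10014418 (1.96) and on 2R from 2885829 to 2887203 (1.67). The second of replicate 1 and the first of replicate 2 were also without overlap in the replicate-set list.

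The replicate-set list was broader than either replicate list. It held 7052 clusters over 39.2 Mb, or 32.6% of the main arms. It contained 99.98% of the sequence found in both replicate lists and 95.2% of that found in either. Of its own length, 71.2% lay in both lists and 93.8% in either. Clusters without a base in either replicate list numbered 862 (12.2%), with a median length of 1225 bp and a median score of 0.474. Many were therefore shorter than 1301 bp, the shortest cluster of the replicate lists. On X these made up 18.4% of the clusters (291), against 8.37% on 2R to 11.3% on 3R among the large autosomal arms and 15.4% on chromosome 4 (10 clusters).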

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

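Alternatives added after the data were seen were the upper 25% by score for comparisons of arms, merging under 10 kb, holding autosomal clusters alone, or X and autosomal clusters alike, to the X floor (the 5th percentile of the X score within a length class), rotating the X block, leaving out 2 Mb at the centromere, and every alternative for long regions, region density and X agreement. The Jaccard index of the replicates stayed far above the shifted lists in all 4 alternatives, from 0.565 in the upper 25% by score to 0.735 after merging under 1 kb. Cluster counts were 3214, 3400 and 3527 in the upper 50% by score for replicate 1, replicate 2 and the replicate set, and merging under 1 kb left 4645 in the last. Shared clusters of replicate 1 came to 79.0% with 50% of the cluster covered, 58.6% with 50% of both covered, 77.8% in the upper 50% and 74.2% in the upper 25%; for replicate 2 these were 76.2%, 55.3%, 76.2% and 72.8%. The score correlation was 0.745 for reciprocal pairs. Replicate-set clusters overlapping both lists made up 62.2%, or 91.9% in its upper 50% and 53.2% with 50% of the cluster covered. The lower coverage of X kept its direction in all alternatives and missed the threshold in the replicate-set list (-4.03 points). It was -4.81 with X and autosomal clusters alike held to the X floor. Holding autosomal clusters alone to it, a cut that narrows the gap by construction, gave -3.21 (permutation p = 0.0457), and -1.60 with the floor at the 10th percentile, which also missed the threshold (permutation p = 0.303). The shortage of long X regions passed in all alternatives tried for it. Region density on X minus autosomes, not called in the main comparison (0.688 per Mb), was 4.02 per Mb without replicate 1 and 7.14 without replicate 2, where it was called. It was also called at 15.8 in the replicate-set list, 10.5 in the union, 15.0 with X and autosomal clusters alike held to the X floor and, reversed, at -4.70 in the upper 25%, and was -0.155, not called, with 100-kb windows. The value of 21.4 with autosomal clusters alone held to the floor had its direction set by construction. The 15.0 was pushed the same way, since a floor taken from X scores removes more autosomal clusters. It left 50.2 regions per Mb on X and 35.2 on the autosomes. The centromere-side difference ranged from -3.54 to -2.96 points with 1 replicate left out, and was called without replicate 2. It was also called in the replicate-set list (-3.85), the union (-3.73), the upper 50% (-2.39) and 100-kb windows (-3.09), and turned to 0.258 without the 2 Mb at the centromere, so it rests on those windows. Where no cause is named, the cause was not tested. Alternatives planned for genomic features, gene length and gene lists were not run, for want of an annotation of release 5. No paired analysis was possible because the inputs, which share numbers with the ChIP libraries, have no lists of their own. Unknown depth limits every statement on short or weak clusters.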

Other observations

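Of the tests reported here, only the one leaving out sequence near the centromere, for coverage of X, was chosen before its result was seen. Some stretches of the main arms carried no cluster in either replicate list. These stretches and windows were picked after their values were seen. Among the 15 longest, those wholly outside the 2 Mb of their arm nearest the centromere were on 3L from 18167140 to 18611845 (444706 bp), on 3R from 2485886 to 2878443 (392558 bp), on 2R from 2127980 to 2497823 (369844 bp), on 2L from 1259002 to 1609157 (350156 bp), on 3R from 12481255 to 12808671 (327417 bp), on X from 2683474 to 2994747 (311274 bp) and on X from 7218193 to 7502226 (284034 bp). At the other end of the range, the 500-kb windows with the highest coverage were on 3R from 1000001 to 1500000 (65.7% in replicate 1 and 65.9% in replicate 2), 3R from 19500001 to 20000000 (64.2% and 64.4%), 3R from 5500001 to 6000000 (61.2% and 65.7%) and 2R from 17000001 to 17500000 (60.9% and 61.4%). In the last lay the longest region of both lists. A gene annotation of release 5 would show which genes fill these stretches, and it was not used here.

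The lower coverage of X than of the large autosomal arms, here called the autosomes without chromosome 4, has several candidate explanations. Sequence near the centromere did not account for it, since without the third of each arm nearest the centromere X minus autosomes was -9.08 points (permutation p = 1e-05). Domains broken into pieces by the caller were not the whole cause, at the gap size tested, since joining clusters under 10 kb apart left -7.25 points (permutation p = 0.00467). Joining raised mean coverage from 16.4% to 28.0% on X and from 24.99% to 35.2% on the autosomes. Relative to coverage the gap therefore shrank, and such breaks may account for part of it. The lower end of the scores was higher on X. Among clusters under 1600 bp the 5th percentile of the score was 0.441 on X and 0.306 on the autosomes in replicate 1, and 0.496 against 0.439 in replicate 2. When X and autosomal clusters alike were held to the X floor of their length class, the difference was -6.02, -4.81 and -4.51 points for floors at the 1st, 5th and 10th percentile (permutation p = 0.00036, 0.00244 and 0.00322). A gap thus remained at a common floor, so far as scores on X and the autosomes share a scale. The floor came from X clusters that had been called, so the cut cannot restore lost ones. Of the replicate-set clusters on X, 18.4% lay in neither replicate list, against 8.37% on 2R to 11.3% on 3R among the large autosomal arms. These X clusters had a median length of 1247 bp, and the shortest cluster in the replicate lists was 1301 bp. Many were thus too short for those lists, so this share does not measure lost weak clusters. How much of the gap comes from the loss of weak X clusters is open. Agreement of the replicates also bears on the main value, which counts only sequence found in both lists. The replicates shared less on X, which lowers that value there. In the union the difference was -5.93 points (permutation p = 0.00833), and in the replicate-set list -4.03 points (permutation p = 0.0723). Each replicate list alone is free of this filter, and gave -4.91 points in replicate 1 and -9.61 points in replicate 2. Lower agreement on X may thus account for part of the gap, though the value of replicate 2 goes the other way. The design has no group that sets apart a biological explanation, such as the sex of the flies, and none was tested.

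The shortage of long X regions was put to the same tests. Without the third of each arm nearest the centromere, X minus autosomes was -7.56 points (permutation p = 1e-05). With X and autosomal clusters alike held to the X floor at the 5th percentile, the difference for regions of 10 kb and over was -6.48 points (permutation p = 1e-05), and it was -6.72 and -6.11 at the 1st and 10th. Joining clusters under 10 kb apart left -7.60 points (permutation p = 0.0037). Joining raises coverage on X and autosomes alike, so this value is not on the scale of the difference before it. Moving the block of X windows along the arms laid end to end gave a difference as large at 1 of 236 positions, the true one. Leaving out the third nearest the centromere and joining clusters argue against that sequence, and against breaks of that size, as the whole cause. The means behind the joined value are not given here, so how far the shortage shrank relative to coverage is not known. Such breaks may account for part of it. The common floor cannot decide on lost weak clusters here, because a long domain detected weakly could be listed as shorter clusters. Moving the X block bears on none of these causes. The main value again counts only sequence found in both lists. Its ratio of autosomes to X was 4.21, against 2.20 in replicate 1, 5.00 in replicate 2 and 1.91 in the replicate-set list. In points the gap was -6.89 in the main comparison, -9.48 in the union and -8.02 in the replicate-set list. How much lower agreement on X adds to the shortage is therefore open. A lower read depth on X that shortens domains at their edges could not be tested without reads, and a difference in the marking of X itself remains an untested hypothesis.

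Replicate 1 X clusters were found in replicate 2 less often than their length would give. The share was 74.5% on X, while replicate 1 autosomal clusters drawn to the same lengths were found in 84.5% (95% of 10000 draws between 82.7 and 86.2), which argues against shorter clusters on X as the whole cause. In the other direction, X clusters of replicate 2 were found in 85.1% and length-matched autosomal ones in 77.5%. The score of shared clusters, replicate 1 minus replicate 2, was 0.0884 higher on X than on the autosomes (-0.0161 ± 0.0926 over 45 windows against -0.104 ± 0.108 over 192; SD; permutation p = 1e-05). This is consistent with X standing relatively higher in replicate 1, by a shift between libraries whose source (the input, the flies or the calling) cannot be separated with 1 input per replicate. The median score difference over pairs was -0.358 on chromosome 4 (41 pairs), from -0.195 on 2L to -0.0997 on 3L among the large autosomal arms, and -0.0369 on X, and chromosome 4 was not tested.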
